A study of Homo sapiens with 6 samples.

How the data were processed

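Messenger RNA from 6 samples of T24 cells was measured by RNA sequencing. T24 is an established human bladder carcinoma cell line. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and the cDNA was ligated to adapters and amplified by PCR. The labels put 3 libraries in an empty-vector lentivirus group and 3 in a CARM1 lentivirus group, and the titles number the libraries of each group 1 to 3. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

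The authors deposited 1 table of FPKM values (fragments scaled to the length of the transcript and to the mapped fragments of the library), with 1 column per library and 1 line per gene. The genome build was GRCh38.p14, per the submitters' processing notes. The aligner, the quantifier, their versions, the gene annotation and whether strand was used were not given in the sources used here. The table lists 19974 genes by Ensembl identifier, and all 6 columns were used. Each identifier was found in GENCODE 29, where 19922 of them are protein-coding. In 27 lines the gene symbol had been turned into a date, and it was restored from the identifier. For the 15 symbols carried by more than 1 identifier, the identifier with the highest mean FPKM was used for named genes and gene lists, while the test over all genes and the families by symbol kept every identifier. No gene above 0 had the same value in all 6 libraries, and 3161 genes were at 0 in all 6.

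FPKM values already divide by gene length and by the mapped fragments of a library, so a large change in a few abundant genes shifts all others. The total FPKM also depends on transcript lengths, and it differed between the groups. Depth was looked for in the low values, since whole reads leave steps. Among the 15 pairs of libraries, at most 12.9% of the low genes shared 1 ratio within 0.01 on the log2 scale, so no steps were found. The sequencing depth is therefore unknown, no counting intervals were computed and no count test was run. Precision rests on the spread of 3 libraries per group.

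Values were analysed as log2(FPKM + 1), with no further scaling, in R 4.3.3 with limma 3.58.1. Fold changes are on this scale, which understates the change of low genes, and are CARM1 minus empty vector. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 11553 genes. The model was a linear fit with 1 term for the group and a moderated variance with an intensity trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05 with no fold limit. CARM1 and ENO1 were also tested by an exact permutation test of 3 against 3 values. Ratios of mean FPKM are given as folds, and errors are SD over 3 libraries or the standard error (SE) of the fold change.

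The grouping, the test, the rule for named genes, 27 gene lists and most alternatives were fixed before the data were examined. The lists cover arginine methyltransferases, CARM1 partners and substrates, glycolysis, ferroptosis suppressors and drivers, iron handling, NRF2 targets, the ATF4 amino acid response, endoplasmic reticulum chaperones, interferon-stimulated genes, NF-kB cytokines and feedback genes, and the hypoxia response. They also cover cholesterol synthesis, fatty acid synthesis and desaturation, the cell cycle, p53 targets, luminal and basal urothelial markers, mesenchymal and matrix genes, nuclear oxidative phosphorylation genes, mitochondrial DNA transcripts, ribosomal proteins, replication-dependent histones, immediate early genes, and markers of fibroblasts, leukocytes and endothelium. For each list, members called higher and lower were counted over all tested genes and again adjusted over the list alone. The 24 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry, which asks whether a list moves 1 way on balance without comparing it with other genes, were alternatives. With an estimated correlation camera also refers its statistic to the residual degrees of freedom of the libraries, which are few.

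The named genes are CARM1, ENO1, the 10 largest rises and 10 largest falls, up to 4 called members of each list by smallest adjusted p, and GPX4, SLC7A11, ACSL4, TFRC, FTH1, HMOX1 and AIFM2 whether called or not. The largest changes were taken among called genes with a mean of at least 2 FPKM in the higher group and with no overlap between the groups. XIST and Y-linked genes were left out, and some genes that the rule names are not reported here. Of the 113 named genes, 50 share exon sequence with another gene in GENCODE 29, found with bedtools 2.31.1, and in 33 of these a partner lies on the opposite strand. Without strand information, reads of such partners cannot be told apart.

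The scripts were tested on simulated data for the comparison of CARM1 with empty vector, with 200 of the 11553 genes changed by known folds. The test called 18 of 67 genes changed 1.2-fold (26.9%), 52 of 67 changed 1.5-fold (77.6%) and 61 of 66 changed 2-fold (92.4%), in the right direction. Of 143 calls, 12 were unchanged genes. Far more genes were called in the data, and the adjustment is stricter where few genes change. These shares therefore do not give the detection limit of the real comparison. Alternatives were pseudocounts of 0.1 and 0.25, no filter, a filter of 5 FPKM, equal library totals, median-of-ratios scaling, quantile normalization, no intensity trend, array weights, the replicate number as a block, each library left out in turn, an adjusted p of 0.01 and a log2 fold limit of 1. A scaling to equal totals outside the mitochondrial genome, removal of each library's trend on GC content and transcript length by loess with a span of 0.3, and lists without shared members were added after seeing the data. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.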

Results

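The transcriptome of T24 cells, an established human bladder carcinoma line, was compared between 3 libraries from cells given a CARM1-overexpressing lentivirus and 3 libraries from cells given the empty vector. CARM1 is a protein arginine methyltransferase that acts as a transcriptional coactivator. The design was a screen for genes that respond to its overexpression, and the title of the series ties CARM1 to ferroptosis, an iron-dependent cell death driven by lipid peroxidation, and to the glycolytic enzyme ENO1. Total FPKM ran from 359393 to 364371 in the empty-vector libraries and from 371925 to 374948 in the CARM1 libraries, and the depth in reads is unknown. Between 11526 and 11543 genes reached 1 FPKM in the empty-vector libraries and between 11314 and 11324 in the CARM1 libraries. Transcripts of the mitochondrial genome took 7.22% ± 0.0761 of the FPKM with empty vector and 6.69% ± 0.105 with CARM1 (SD, n = 3 each). Libraries of 1 group correlated at r = 0.993 to 0.994 across genes and libraries of different groups at 0.955 to 0.958, over genes that are not independent replicates. The median coefficient of variation of the 1392 genes with a mean over 50 FPKM was 3.19% with empty vector and 3.35% with CARM1. Below, means are given ± SD with n = 3 per group.

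CARM1 was higher in all 3 libraries of the CARM1 group. Its FPKM was 16.26, 17.85 and 17.04 in the empty-vector libraries and 34.9, 39.2 and 42.4 in the CARM1 libraries, with means of 17.1 ± 0.794 and 38.8 ± 3.75, a 2.28-fold difference. The log2 fold change was 1.14 (SE 0.0723, limma adjusted p = 4.34e-06). The exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. CARM1 (ENSG00000142453) lies on chromosome 19 from 10871513 to 10923070 on the plus strand of GRCh38, and its exons overlap YIPF2 on the opposite strand. FPKM does not separate introduced CARM1 from the cell's own.

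The difference between the groups reached most expressed genes, and its large changes were mostly falls. The largest rise on the log2(FPKM + 1) scale was HMOX1, heme oxygenase, which releases iron from heme, from 73.0 ± 1.52 to 418.8 ± 12.4 FPKM, a 5.74-fold difference (log2 fold change 2.50, SE 0.0353, limma adjusted p = 3.05e-09). It was followed by the drug efflux pump ABCB1 (7.87 ± 0.0797 to 39.4 ± 1.85 FPKM), the inducible heat shock protein HSPA6 (1.66 ± 0.303 to 9.47 ± 0.778) and the extracellular chaperone CLU (16.3 ± 2.44 to 63.8 ± 1.23). The helix-loop-helix inhibitors ID3 and ID1 rose 3.81-fold and 3.21-fold, the small heat shock protein CRYAB 5.77-fold, the lipoprotein lipase inhibitor ANGPTL4 2.88-fold and the histone HIST1H2BK 2.66-fold. SKP1, a core subunit of SCF ubiquitin ligases, rose from 31.9 ± 15.5 to 103 ± 30.7 FPKM with a wide spread in both groups (limma adjusted p = 0.00153).

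The largest falls on the same scale included genes for secreted and cell-surface proteins. The acute-phase protein SAA1 fell from 30.4 ± 1.53 to 2.58 ± 0.15 FPKM (log2 fold change -3.13, SE 0.0645, limma adjusted p = 1.46e-08), and the cytokine CSF2, or GM-CSF, from 252.7 ± 2.1 to 30.5 ± 2.14 (-3.01, SE 0.0506, limma adjusted p = 5.34e-09). PTGES, which makes prostaglandin E, went from 14.9 ± 0.619 to 0.993 ± 0.342 FPKM, and the integrin ITGB3 from 22.8 ± 1.21 to 2.24 ± 0.272. The cytokine subunit EBI3 (log2 fold change -2.84), the sialic acid receptor SIGLEC15 (-2.83), the metalloprotease ADAM8 (-2.80), the chemokine CCL20 (-2.76), the cation channel TRPV3 (-2.65) and the decoy receptor TNFRSF6B (-2.62) fell as well, with limma adjusted p-values of at most 2.21e-06. SAA1, HSPA6 and HIST1H2BK have near-identical relatives and TNFRSF6B shares exons with a readthrough transcript, so the split of reads among them is uncertain. Of 11553 tested genes, 7302 (63.2%) were called by limma, 4411 higher and 2891 lower with CARM1. Among those with an absolute log2 fold change of at least 1, 55 were higher and 372 lower. The groups did not overlap in 7910 genes (68.5%), where chance gives 10%. The share of calls that were higher depended on the scaling: it was 60.4% as deposited, and 49.0% under median-of-ratios scaling, with 3413 higher and 3546 lower. That scaling moved the median log2 fold change of all genes from 0.08 to 0.00.

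**Figure D1:**
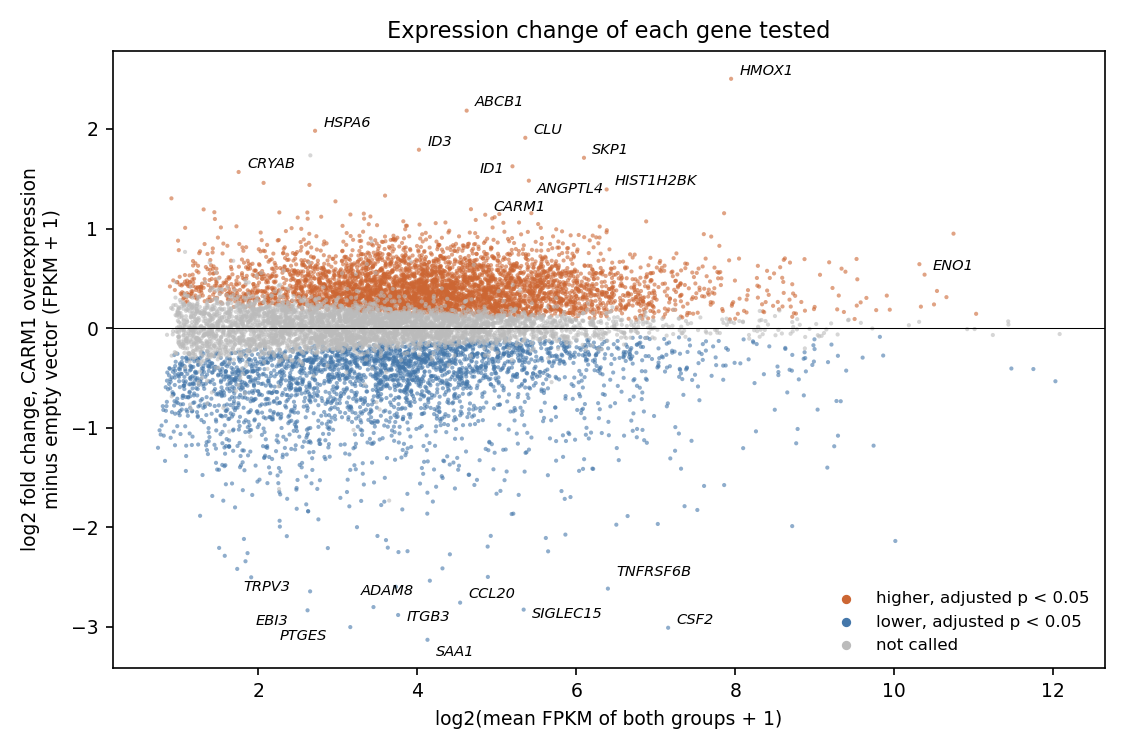
Log2 fold change of each of the 11553 tested genes (CARM1 overexpression minus empty vector, FPKM + 1) against log2 of the mean FPKM of both groups + 1, each point a gene, orange for the 4411 called higher, blue for the 2891 called lower and grey for genes not called. The named points are CARM1, ENO1 and the 10 largest rises and falls, and the falls reach -3.13 while the largest rise is 2.50.

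Of the 27 gene lists, 24 had enough tested members, and camera called 11 of them, 5 toward higher and 6 toward lower expression. With an estimated inter-gene correlation camera called 0 of the 24 after adjustment, although 7 were under an unadjusted p of 0.05, and fry called 22. Under the 4 scalings the median of each list kept its sign except those of 2 lists, the basal urothelial markers and the mitochondrial DNA transcripts. Counts of members called higher and lower are as deposited, and some moved by over 1.5 times under median-of-ratios scaling. They were then 3 and 13 for endoplasmic reticulum chaperones and for cholesterol synthesis, 4 and 11 for fatty acid synthesis and desaturation, 3 and 12 for immediate early genes, 3 and 3 for histones, 1 and 7 for luminal markers, 1 and 4 for basal markers, 0 and 21 for mesenchymal and matrix genes and 3 and 5 for mitochondrial DNA transcripts. For iron handling they were 3 and 9 under quantile normalization. Small medians moved too. Over the refits the median ran from -0.17 to -0.02 for hypoxia genes, -0.20 to -0.05 for cholesterol synthesis, -0.18 to -0.03 for p53 targets, -0.33 to -0.13 for immediate early genes, -0.15 to -0.05 for ribosomal proteins and -0.19 to 0.11 for basal markers. It ran from 0.05 to 0.24 for CARM1 partners, 0.11 to 0.29 for glycolysis, 0.16 to 0.32 for ferroptosis drivers and 0.17 to 0.32 for nuclear oxidative phosphorylation genes.

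**Figure D2:**
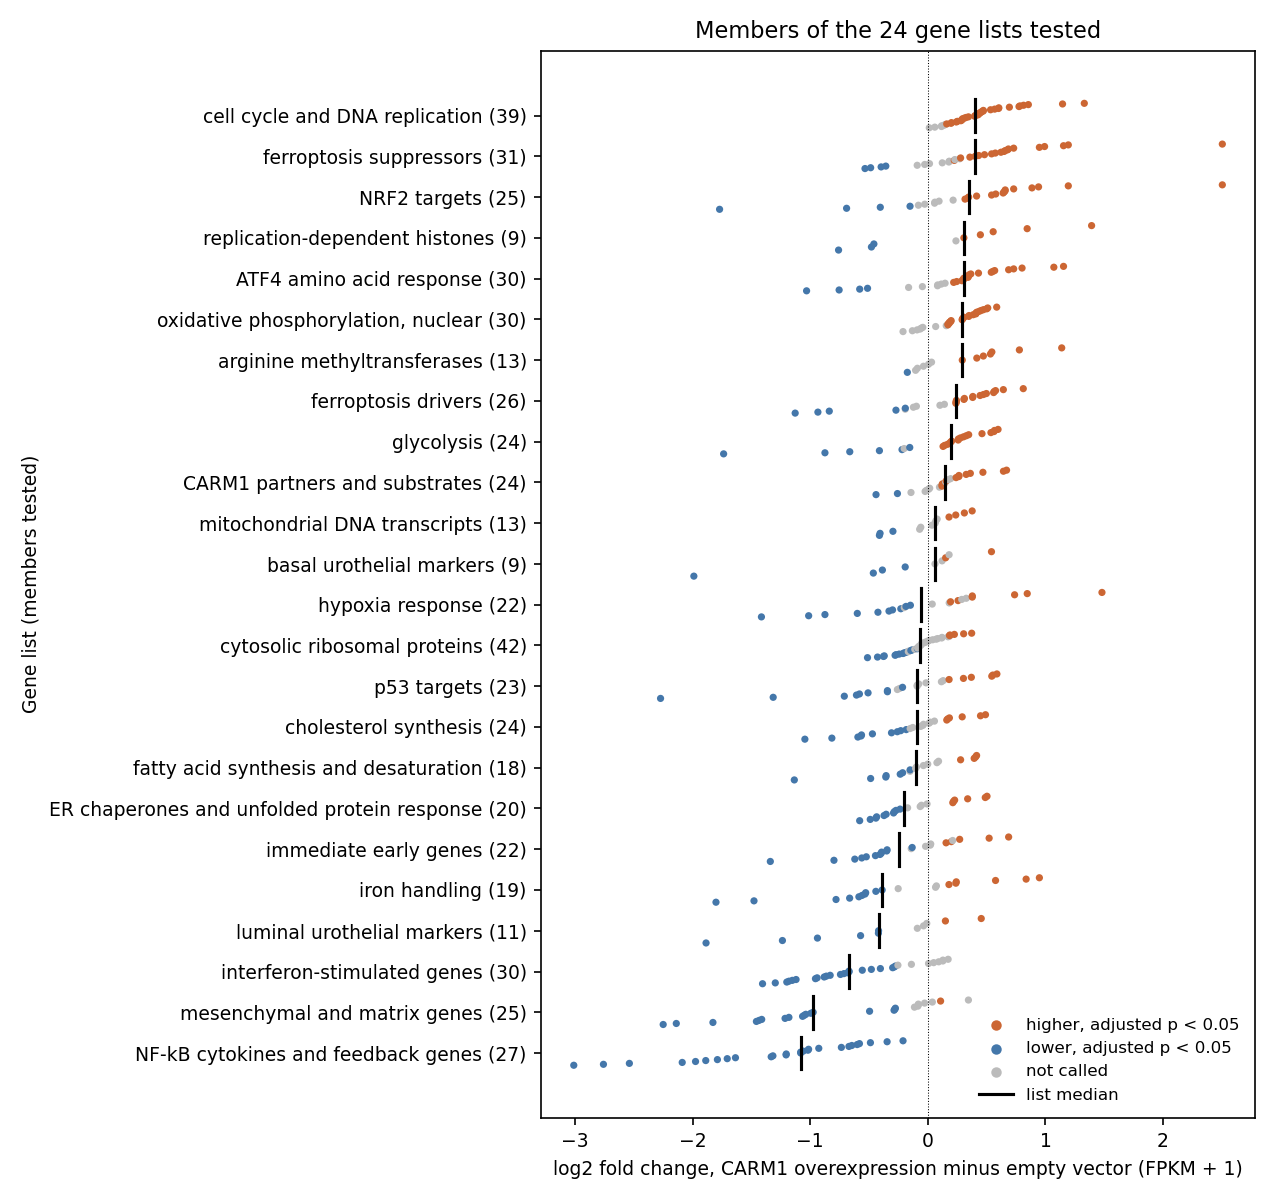
Log2 fold change (CARM1 overexpression minus empty vector, FPKM + 1) of the tested members of the 24 lists, each point a gene, orange for called higher, blue for called lower and grey for not called, with a black bar at the list median and the number of tested members in brackets. The median runs from -1.08 in the NF-kB list to 0.40 in the cell cycle list.

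ENO1, the glycolytic enolase named in the title, rose with CARM1, and several other glycolysis genes rose beside it. ENO1 (ENSG00000074800, chromosome 1 from 8861000 to 8879250 on the minus strand of GRCh38) went from 1087.8 ± 20.4 to 1578.1 ± 12.6 FPKM, a 1.45-fold difference. Its log2 fold change was 0.54 (SE 0.0277, limma adjusted p = 1.41e-06), and the exact permutation test gave p = 0.1, the smallest possible. Of 24 glycolysis genes, 17 rose, 6 fell and 1 was not called, and adjusted over the list alone the counts were 17 and 6. Under median-of-ratios scaling 13 rose and 6 fell, and under quantile normalization 12 rose and 6 fell. PGAM1 (514 ± 15.7 to 777.7 ± 16.9 FPKM), PGK1 (180 ± 1.48 to 266.9 ± 1.36) and PKM (850 ± 15.8 to 1067 ± 37.1), which act near ENO1 in the pathway, rose, while the glucose transporter SLC2A3 fell from 15.99 ± 0.0347 to 8.26 ± 0.116. Camera did not call the list as a whole against other genes (median log2 fold change 0.20, camera adjusted p = 0.227, and adjusted p = 0.414 with an estimated correlation). Fry, which makes no comparison with other genes, called it higher (fry adjusted p = 0.000582). ENO1, PGK1 and PGAM1 have processed pseudogenes, and ENO1 overlaps an antisense gene, so part of their reads is uncertain.

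Most tested members of the fixed list of ferroptosis suppressors rose, with GPX4 and FTH1 among the exceptions. Of 31 tested suppressors 19 rose, 4 fell and 8 were not called, and adjusted over the list alone the counts were 19 and 4. Their median log2 fold change was 0.40 (camera adjusted p = 0.00572), and adjusted p = 0.126 with an estimated correlation. HMOX1 is in the fixed list of suppressors, although it releases iron from heme. Beside HMOX1, the ferritin light chain FTL rose from 1171 ± 23.7 to 2261 ± 11.3 FPKM. Both subunits of the cystine importer that feeds glutathione synthesis rose, SLC3A2 from 143 ± 3.75 to 319.6 ± 15.1 and SLC7A11 from 5.76 ± 0.332 to 10.2 ± 0.969. TXNRD1, thioredoxin reductase, rose from 319 ± 5.0 to 504 ± 3.26, and AIFM2 (FSP1), which regenerates reduced ubiquinone, from 9.71 ± 0.833 to 16.1 ± 0.876. GPX4, the peroxidase that reduces lipid hydroperoxides, fell from 159.6 ± 16.4 to 120.6 ± 7.45 FPKM (log2 fold change -0.40, SE 0.0761, limma adjusted p = 0.00185).

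Among 26 tested ferroptosis drivers 16 rose, 5 fell and 5 were not called, and adjusted over the list alone 17 rose and 5 fell. Without CARM1 replicate 3, and also with a filter of 5 FPKM, 15 rose and 3 fell. Camera did not call the list against other genes (median 0.24, camera adjusted p = 0.172, and adjusted p = 0.258 with an estimated correlation), while fry called it higher (fry adjusted p = 6.38e-05). The glutamine transporter SLC1A5 rose by a log2 fold change of 0.81 (SE 0.0451), the transferrin receptor TFRC by 0.58 (SE 0.0326) and the outer mitochondrial membrane channel VDAC2 by 0.56 (SE 0.0389), whereas SAT1, a polyamine acetyltransferase, had a log2 fold change of -0.84 (SE 0.0376). ACSL4, which loads membranes with polyunsaturated fatty acids, was at 63.7 ± 4.68 and 59.4 ± 1.91 FPKM and was not called (limma adjusted p = 0.161). It was called lower under median-of-ratios scaling (limma adjusted p = 0.0165), under quantile normalization (0.0114) and without empty-vector replicate 2 (0.0418).

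Iron handling genes fell more often than they rose. Of 19 tested members 6 rose, 10 fell and 3 were not called, and adjusted over the list alone the counts were 6 and 11. The heavy chain of ferritin, FTH1, fell from 4938 ± 109 to 3409 ± 86.7 FPKM while FTL rose, and the mitochondrial iron importer SLC25A37 fell from 72.5 ± 2.85 to 25.4 ± 1.89. TFRC rose from 109.7 ± 1.16 to 163.9 ± 3.56 FPKM. The list median was -0.39 (camera adjusted p = 0.0573, and adjusted p = 0.197 with an estimated correlation). It was -0.17 with no filter on low values, -0.19 with a filter of 5 FPKM and -0.24 under quantile normalization. Both ferritin genes have many processed pseudogenes, and how reads were split among them is not known. The list was called without empty-vector replicate 1 (camera adjusted p = 0.0462).

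**Figure D3:**
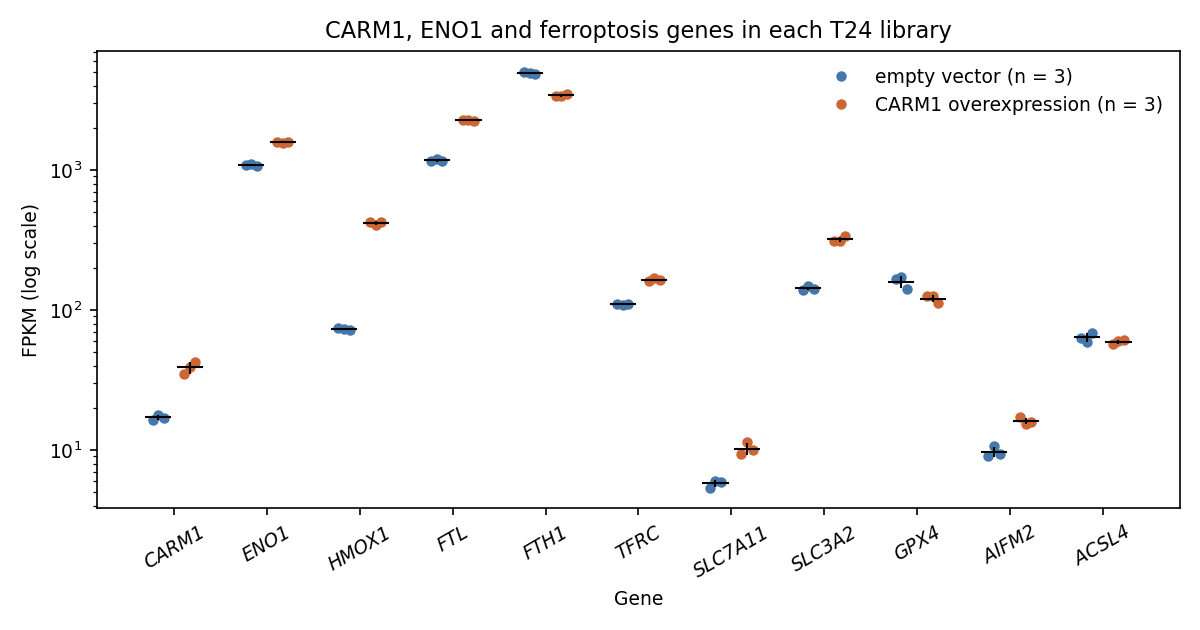
FPKM of CARM1, ENO1 and 9 ferroptosis genes on a log axis, each point a library, blue for empty vector and orange for CARM1 overexpression, with a horizontal bar at the mean of 3 libraries and a vertical bar of 1 SD on each side. HMOX1 lies at 73.0 and 418.8 FPKM, FTL and FTH1 move in opposite directions, and the ACSL4 libraries of the 2 groups overlap.

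Most tested antioxidant and amino acid response genes rose. Of 25 tested targets of NRF2, the transcription factor of the electrophile response, 15 rose, 4 fell and 6 were not called, with 15 and 4 adjusted over the list alone. SRXN1, sulfiredoxin, rose from 26.1 ± 1.07 to 51.0 ± 1.17 FPKM, while the exporter ABCC3 fell from 8.40 ± 0.34 to 1.75 ± 0.0993. The NRF2 list had a median of 0.35 (camera adjusted p = 0.0313, and adjusted p = 0.166 with an estimated correlation). Of 30 tested genes of the ATF4 amino acid response 20 rose, 4 fell and 6 were not called, with 20 and 4 adjusted over the list alone. The amino acid transporter SLC7A5 rose 2.12-fold, the serine synthesis enzyme PSAT1 1.76-fold and the secreted glycoprotein STC2 1.49-fold. The ATF4 list had a median of 0.30 (camera adjusted p = 0.0323, and adjusted p = 0.2503 with an estimated correlation). Some members of both lists are also in the ferroptosis lists, and without shared members neither list was called (camera adjusted p = 0.424 and 0.165), nor was either with a filter of 5 FPKM (0.0541 for both).

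All 27 tested NF-kB cytokines and feedback genes fell. They were called lower, also when adjusted over the list alone, with a median log2 fold change of -1.08. Besides CSF2 and CCL20, the cytokine LIF fell from 157 ± 0.693 to 41.6 ± 0.715 FPKM, TNFAIP2 from 49.0 ± 0.641 to 15.1 ± 0.416 and TNFAIP3 (A20), a feedback inhibitor of the pathway, from 75.9 ± 2.51 to 29.5 ± 0.54. Camera called the list (adjusted p = 1.19e-16, and adjusted p = 0.0879 with an estimated correlation). Interferon-stimulated genes went the same way, with 22 of 30 tested members lower, 0 higher and 8 not called, and 22 lower adjusted over the list alone. IFI27 fell from 162 ± 6.42 to 72.7 ± 8.07 FPKM, the membrane-bound antiviral protein IFITM3 from 140 ± 2.9 to 84.9 ± 5.21, OAS2 from 6.03 ± 0.43 to 1.86 ± 0.118 and IFIT2 from 9.27 ± 0.669 to 3.47 ± 0.358. The interferon list had a median of -0.67 (camera adjusted p = 4.47e-07, and adjusted p = 0.1004 with an estimated correlation). The leukocyte markers, which could report other cells, had a median of 0.0541 FPKM with empty vector and 0.0437 with CARM1.

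Among 22 tested immediate early genes 5 rose, 12 fell and 5 were not called, with 5 and 12 adjusted over the list alone. EGR1 fell from 24.1 ± 0.527 to 8.97 ± 1.37 FPKM, JUNB from 66.7 ± 2.98 to 37.9 ± 0.957 and the phosphatase DUSP5 from 46.6 ± 2.56 to 31.2 ± 1.21, while JUN rose from 52.2 ± 2.25 to 75.4 ± 2.13. The list median was -0.24 (camera adjusted p = 0.0274, and adjusted p = 0.166 with an estimated correlation).

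Most tested mesenchymal and matrix genes fell. Of 25 tested members 1 rose, 17 fell and 7 were not called, with 1 and 17 adjusted over the list alone. Fibronectin, FN1, fell from 1684.1 ± 40.0 to 381.4 ± 3.6 FPKM (log2 fold change -2.14, SE 0.0295, limma adjusted p = 3.05e-09), and the collagen COL6A1 from 286 ± 3.94 to 79.9 ± 1.84. The urokinase PLAU fell by 1.41 (SE 0.0351) on the log2 scale. The list had a median of -0.98 (camera adjusted p = 7.54e-08, and adjusted p = 0.0705 with an estimated correlation). With no filter on low values the median was -0.50 over 27 members.

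Only part of the urothelial differentiation markers passed the filter, 11 of 21 luminal and 9 of 20 basal ones, and 6 of the luminal ones fell. Of 21 luminal markers 11 were tested, of which 2 rose, 6 fell and 3 were not called, with 2 and 7 adjusted over the list alone. The epithelial transcription factor ELF3 fell from 2.79 ± 0.138 to 0.0251 ± 0.00622 FPKM, KRT19 from 5.57 ± 0.931 to 1.77 ± 0.127, KRT7 from 469 ± 11.0 to 350.9 ± 11.9 and the receptor ERBB3 from 2.64 ± 0.3 to 0.898 ± 0.101. The luminal list had a median of -0.42 (camera adjusted p = 0.0164, and adjusted p = 0.166 with an estimated correlation). With a filter of 5 FPKM the luminal list was not called (median -0.06, camera adjusted p = 0.133), and of 6 tested members 1 rose and 2 fell. Its median was -0.04 over 19 members with no filter and -0.22 with GC and length trends removed. Of 9 tested basal markers 2 rose, 4 fell and 3 were not called, with 2 and 4 adjusted over the list alone. The laminin chain LAMB3 fell from 418 ± 4.42 to 319.8 ± 13.8 FPKM, CD44 fell from 379 ± 11.0 to 275.7 ± 28.0, and COL17A1 rose from 2.70 ± 0.378 to 4.37 ± 0.239. The basal list had a median of 0.06, which turned to -0.03 under median-of-ratios scaling and under quantile normalization, while camera's direction was down (camera adjusted p = 0.299, and adjusted p = 0.561 with an estimated correlation).

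Most tested cell cycle and replication genes rose. Of 39 tested members 33 rose, 0 fell and 6 were not called, with 33 and 0 adjusted over the list alone. CDC25A, the phosphatase that activates cyclin-dependent kinases, rose from 5.88 ± 0.571 to 16.3 ± 0.616 FPKM, the mitotic transcription factor FOXM1 from 35.9 ± 0.707 to 62.4 ± 2.23, UHRF1, which maintains DNA methylation, from 19.4 ± 0.407 to 35.9 ± 1.55, and the replicative helicase subunit MCM4 from 61.9 ± 2.22 to 94.5 ± 2.04. The list had a median of 0.40 (camera adjusted p = 4.47e-07, and adjusted p = 0.175 with an estimated correlation). Among 9 tested members of the histone list 5 rose, 3 fell and 1 was not called, with the same 5 and 3 adjusted over the list alone. Without empty-vector replicate 1 or 3 or CARM1 replicate 1, 3 rose and 3 fell. Beside HIST1H2BK, HIST2H2AA3 rose by 0.56 (SE 0.0771) on the log2 scale, and H1F0 and HIST2H2BE had log2 fold changes of -0.48 (SE 0.0423) and -0.76 (SE 0.117). H1F0 is in the fixed list of replication-dependent histones, but it is a replication-independent linker histone with a polyadenylated message. Replication-dependent histone messages mostly lack the poly(A) tail the libraries selected, and the histone list was not called (median 0.31, camera adjusted p = 0.718, and adjusted p = 0.728 with an estimated correlation).

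Many nuclear genes of oxidative phosphorylation rose, and mitochondrial DNA transcripts were mixed. Of 30 tested nuclear genes 22 rose, 0 fell and 8 were not called, with 22 and 1 adjusted over the list alone. Under median-of-ratios scaling 15 rose and 2 fell, and under quantile normalization 15 rose and 3 fell. The ATP synthase subunits ATP5F1B and ATP5PB rose from 269 ± 8.84 to 359.2 ± 3.44 and from 32.5 ± 1.5 to 49.3 ± 1.96 FPKM, SDHB from 40.0 ± 0.623 to 52.6 ± 1.28 and COX5A from 46.3 ± 1.88 to 59.3 ± 1.21. The list had a median of 0.29 (camera adjusted p = 0.0135, and adjusted p = 0.258 with an estimated correlation). It was not called under quantile normalization (camera adjusted p = 0.0595). Of the 13 mitochondrial DNA transcripts 4 rose, 3 fell and 6 were not called, with 4 and 3 adjusted over the list alone. MT-ND4, MT-ND4L, which overlaps it, and MT-ND1 had log2 fold changes of -0.41 (SE 0.0293), -0.41 (SE 0.0349) and -0.30 (SE 0.041), and MT-CYB one of 0.24 (SE 0.0274), which became -0.073 under quantile normalization. MT-ND4 was not called under quantile normalization, where its log2 fold change was -6.46e-16. That normalization gives each rank the same value in every library. A gene that keeps its rank shows no change there, so that refit cannot test the fall of MT-ND4. The median of 0.06 turned to -0.03 under median-of-ratios scaling, and camera's direction was down (camera adjusted p = 0.769, and adjusted p = 0.854 with an estimated correlation).

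Of 42 cytosolic ribosomal protein genes 5 rose, 13 fell and 24 were not called, with 5 and 11 adjusted over the list alone. Under median-of-ratios scaling 3 rose and 24 fell, with equal totals 5 and 21, and with equal totals outside the mitochondrial genome 5 and 23. Without empty-vector replicate 2, 8 rose and 11 fell. RPL3 fell from 564 ± 18.1 to 436.2 ± 12.9 FPKM, RPL13 from 259 ± 7.36 to 199.5 ± 10.4 and RPS4X from 459 ± 12.1 to 380.6 ± 0.706, while RPSA rose from 680 ± 21.7 to 795 ± 14.9. The median was -0.06 (camera adjusted p = 0.0573, and adjusted p = 0.555 with an estimated correlation). Camera called the list lower under median-of-ratios scaling (adjusted p = 0.0181), without empty-vector replicate 3 (0.0226) and without CARM1 replicate 1 (0.0454). These genes have many processed pseudogenes, so their values are uncertain.

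Lipid synthesis genes were mixed. Of 24 cholesterol synthesis genes 6 rose, 10 fell and 8 were not called, with 6 and 10 adjusted over the list alone. The sterol carrier STARD4 fell from 26.8 ± 0.925 to 12.5 ± 0.776 FPKM, INSIG1, which retains the sterol sensor in the endoplasmic reticulum, from 31.1 ± 2.37 to 17.2 ± 0.545, MSMO1 from 35.3 ± 1.2 to 23.5 ± 0.79 and MVD from 42.0 ± 1.35 to 29.98 ± 0.659. The list had a median of -0.09 (camera adjusted p = 0.0484, and adjusted p = 0.2503 with an estimated correlation). That call was lost without empty-vector replicate 2 (camera adjusted p = 0.0848), CARM1 replicate 1 (0.0653) or CARM1 replicate 2 (0.0588). Of 18 tested genes of fatty acid synthesis and desaturation 4 rose, 7 fell and 7 were not called, with 4 and 7 adjusted over the list alone. The desaturases FADS2 and SCD fell by 0.49 (SE 0.0455) and 0.36 (SE 0.035) on the log2 scale and FADS3 by 1.14 (SE 0.0458), and the elongase ELOVL1 rose by 0.41 (SE 0.0457). The list was not called (median -0.10, camera adjusted p = 0.156, and adjusted p = 0.334 with an estimated correlation). With GC and length trends removed its median turned to 0.05, with 6 members higher and 6 lower, and it was -0.19 under median-of-ratios scaling and -0.17 under quantile normalization.

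Of 20 endoplasmic reticulum chaperones and unfolded protein response genes 6 rose, 10 fell and 4 were not called, with 6 and 10 adjusted over the list alone. HSPA5 (BiP) fell from 299 ± 4.43 to 233.9 ± 2.6 FPKM, HSP90B1 from 544 ± 12.6 to 401.9 ± 6.21 and PDIA4 from 182 ± 0.673 to 129.5 ± 0.588, while calnexin, CANX, rose from 255 ± 2.86 to 361.6 ± 6.17. The list median was -0.20 (camera adjusted p = 0.0573, and adjusted p = 0.197 with an estimated correlation). Among 22 tested hypoxia response genes 7 rose, 10 fell and 5 were not called, and adjusted over the list alone 8 rose and 10 fell. VEGFA fell from 107 ± 1.87 to 39.5 ± 2.31 FPKM and the mitophagy receptor BNIP3 rose from 35.4 ± 0.829 to 64.5 ± 1.5, in opposite directions within 1 list (median -0.06, camera adjusted p = 0.307, and adjusted p = 0.381 with an estimated correlation). Of 23 tested p53 targets 6 rose, 9 fell and 8 were not called, with 6 and 9 adjusted over the list alone. The stress cytokine GDF15 fell from 34.2 ± 2.29 to 6.28 ± 0.133 FPKM, CCNG1 from 50.7 ± 0.725 to 32.9 ± 1.04 and PLK3 from 18.3 ± 1.08 to 10.8 ± 0.415, and the nuclease AEN rose from 17.5 ± 0.599 to 26.8 ± 1.39. The p53 list was not called (median -0.09, camera adjusted p = 0.0953, and adjusted p = 0.231 with an estimated correlation).

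Some other genes of the arginine methyltransferase list, which also holds partners of PRMT5, rose as well. Of 13 tested members, CARM1 included, 7 rose, 1 fell and 5 were not called, with 7 and 1 adjusted over the list alone. PRMT5, the main symmetric dimethylating enzyme, rose from 52.7 ± 1.09 to 73.5 ± 3.45 FPKM, and its partners WDR77 and RIOK1 from 17.97 ± 1.1 to 31.5 ± 0.98 and from 7.45 ± 0.501 to 11.3 ± 0.541. WDR77 overlaps ATP5PB on the opposite strand. The list median was 0.29 (camera adjusted p = 0.164, and adjusted p = 0.258 with an estimated correlation). Of 24 tested CARM1 partners and substrates 13 rose, 2 fell and 9 were not called, and adjusted over the list alone 14 rose and 2 fell. Under median-of-ratios scaling 7 rose and 4 fell, and under quantile normalization 8 rose and 3 fell, with list medians of 0.06 and 0.05. The splicing factors SF3B4 and SNRPB rose by 0.67 (SE 0.0413) and 0.47 (SE 0.0378) on the log2 scale and the corepressor subunit GPS2 by 0.64 (SE 0.0432), with a list median of 0.15 (camera adjusted p = 0.105, and adjusted p = 0.258 with an estimated correlation).

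Markers of other cell types were near the floor in both groups. The median FPKM of 10 fibroblast markers was 0.0449 with empty vector and 0.0272 with CARM1, and that of 10 endothelial markers 0.0776 and 0.0307. COL1A1, which fell from 3.06 ± 0.491 to 1.16 ± 0.21 FPKM, was the 1 tested fibroblast marker. CD68, a lysosomal protein that is not restricted to macrophages, was the 1 tested leukocyte marker of 12 and fell 1.64-fold, from 39.3 ± 0.776 FPKM. Of 2 tested endothelial markers, EGFL7 fell from 10.2 ± 2.77 to 6.75 ± 0.38 (limma adjusted p = 0.0287), a call that was lost without empty-vector replicate 2 (limma adjusted p = 0.0980) or 3 (0.0955) and without CARM1 replicate 2 (0.0722) or 3 (0.0742). It was also lost with no filter on low values (0.0756) and with GC and length trends removed (0.299), where the log2 fold change moved from -0.50 to -0.22.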

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

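The scaling to equal totals outside the mitochondrial genome, the removal of GC and length trends and the lists without shared members were chosen after seeing the data. CARM1 and ENO1 were called higher under all 18 refits. Across these, 84.1% to 99.7% of the called genes stayed called. The lowest share was with the filter of 5 FPKM, which tested 8990 genes, and genes it left out count as not called. The next lowest was 86.3%, under median-of-ratios scaling. With a log2 fold limit of 1, 55 genes were higher and 372 lower. The smaller total follows from the limit's construction, but the split between rises and falls does not. Without 1 library, 4025 to 4138 genes were higher and 2654 to 2710 lower, the log2 fold changes were 1.07 to 1.21 for CARM1 and 0.52 to 0.55 for ENO1, and 10 to 12 lists were called. Of 1991 combinations of 111 other named genes with a setting, 1980 kept direction and call, 7 lost the call and 3 gained it, and MT-CYB reversed to -0.073 under quantile normalization. Most of these genes were named for a large change or a small adjusted p in the same libraries. Their share of kept calls therefore does not measure how stable calls are in general. The 7 lost and 3 gained calls fall on EGFL7, MT-ND4 and ACSL4.

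The replicate numbers are not stated to mark a shared batch, and the deviations of same-numbered libraries correlated at 0.0247, -0.0531 and 0.0661, so not every library went best with its own number. With the replicate number as a block, 4315 genes were higher and 2808 lower, and the cholesterol list was at 0.0549, with no other call of a list or named gene changed.

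Camera adjusted p-values of lists that changed were as follows, and except for shared members the cause was not tested. Without 1 library, cholesterol synthesis ran from 0.0349 to 0.0848 (lost without empty-vector replicate 2 or CARM1 replicate 1 or 2), iron handling from 0.0462 to 0.0789 (called without empty-vector replicate 1) and ribosomal proteins from 0.0226 to 0.147 (called without empty-vector replicate 3 or CARM1 replicate 1). With no filter, CARM1 partners (0.0220) and endoplasmic reticulum chaperones (0.0462) were called, and mitochondrial DNA transcripts reversed (0.992). With a filter of 5 FPKM, NRF2 (0.0541), ATF4 (0.0541) and luminal markers (0.133) were lost, and chaperones (0.0376) and ribosomal proteins (0.0376) were called. Ribosomal proteins were called with equal totals (0.0275), equal totals outside the mitochondrial genome (0.0233), median-of-ratios scaling (0.0181) and trends removed (0.0170). Chaperones were called with median-of-ratios scaling (0.0499), quantile normalization (0.0286) and trends removed (0.0225), as was iron handling with trends removed (0.0237). Quantile normalization lost oxidative phosphorylation (0.0595) and reversed mitochondrial DNA transcripts (0.983). Without shared members, iron handling was called (0.00537), and NRF2 (0.424) and ATF4 (0.165) were not. Cholesterol synthesis shares no member, and its call was lost (0.0532) through the adjustment over lists alone.

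With an estimated correlation 0 lists were called, against 11, with 7 under an unadjusted p of 0.05. That form also rests on few residual degrees of freedom, so the loss is not a measure of correlation alone. The adjusted p was then 0.0705 for matrix genes, 0.0879 for NF-kB, 0.1004 for interferon, 0.126 for ferroptosis suppressors, 0.166 for NRF2, luminal and immediate early genes, 0.175 for the cell cycle, 0.2503 for ATF4 and cholesterol, and 0.258 for oxidative phosphorylation. Fry called 22 lists, among them arginine methyltransferases (0.000220), CARM1 partners (0.000212), glycolysis (0.000582), ferroptosis drivers (6.38e-05), iron handling (8.21e-05), chaperones (6.38e-05), hypoxia (0.000768), fatty acid synthesis (0.00144), p53 targets (5.31e-05), basal markers (0.000574) and histones (0.000947). Depth is unknown, so its limit on low genes could not be set. The simulated 1.2-fold changes were called in 26.9% of 67 genes.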

Other observations

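Of the tests in this part, those of library scaling and of GC content and gene length on the NF-kB list, of GC content and length on the ferritins and of other splits were fixed before their results were seen, and the rest were chosen afterwards. The gene families below were also looked for after the data were seen, and genes named here for the first time were chosen after their values were seen. Genes were grouped by the letters that open their symbol, each identifier counted as a gene, which gave 132 families of at least 10 tested genes. A shared opening does not make every member a relative. Camera called 19 of them, and 0 with an estimated correlation, where the smallest adjusted p was 0.281 and the degrees of freedom are few. Of 49 genes named MRPL, the large subunit of the mitochondrial ribosome, 42 were called higher and 1 lower (camera adjusted p = 6.47e-06, and adjusted p = 0.353 with an estimated correlation), for example MRPL20, from 42.9 to 73.4 FPKM. Of 29 MRPS genes of the small subunit 24 were higher and 1 lower (camera adjusted p = 0.000905, and adjusted p = 0.281 with an estimated correlation), and of 15 TIMM genes of inner membrane import 13 were higher and 0 lower (camera adjusted p = 0.00468, and adjusted p = 0.353 with an estimated correlation). Of 31 POLR identifiers, mostly of RNA polymerase subunits, 25 were higher and 1 lower (camera adjusted p = 0.000428, and adjusted p = 0.281 with an estimated correlation), with POLR3C at 14.7 and 27.0 FPKM. POLR2J3 is in this family as 2 identifiers, of which the 1 with the lower FPKM was called higher and the other was not called. Of 14 PSMD genes, mostly of the proteasome cap, 13 were higher and 0 lower (camera adjusted p = 0.00373, and adjusted p = 0.281 with an estimated correlation), and of 11 UTP genes of ribosome assembly 10 were higher and 0 lower (camera adjusted p = 0.00570, and adjusted p = 0.353 with an estimated correlation). The other families called higher were DDX, EIF, NUP, EXOSC, TRMT, RBM and MCM, with camera adjusted p-values from 0.00373 to 0.0268, and adjusted p-values from 0.281 to 0.353 with an estimated correlation.

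The families called lower were COL, MMP, SEMA, KLF, DHRS and KRT. Of 17 COL genes, collagens apart from the lipid transfer protein COL4A3BP, which was not called, 2 were called higher and 14 lower (camera adjusted p = 6.47e-06, and adjusted p = 0.353 with an estimated correlation), with COL7A1 at 93.1 FPKM with empty vector and 21.3 with CARM1. Of 11 MMP genes, matrix metalloproteinases apart from the opposite-strand gene MMP24OS, which was among the lower, 1 was higher and 9 lower (camera adjusted p = 0.00214, and adjusted p = 0.281 with an estimated correlation), with MMP1 at 21.4 and 3.73 FPKM. Of 12 semaphorins 0 were higher and 10 lower (camera adjusted p = 9.04e-05, and adjusted p = 0.281 with an estimated correlation), with SEMA7A at 84.9 and 46.6. Of 12 KLF genes 0 were higher and 7 lower (camera adjusted p = 0.00996, and adjusted p = 0.353 with an estimated correlation), of 10 DHRS genes 1 was higher and 6 lower (camera adjusted p = 0.0195, and adjusted p = 0.375 with an estimated correlation), and of 10 keratins 1 was higher and 6 lower (camera adjusted p = 0.0195, and adjusted p = 0.423 with an estimated correlation). The keratins were not called under quantile normalization (camera adjusted p = 0.0738). Under the 4 scalings all 19 families kept their direction. Across the 11553 genes, which are not independent replicates, the fold change had a Spearman correlation of -0.195 with GC content and -0.0882 with transcript length.

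The fall of all 27 NF-kB genes was surprising, since CARM1 has been described as a coactivator of NF-kB-dependent transcription. Library scaling does not account for it, as the list median closest to 0 under 4 scalings was -1.13, and neither do trends on GC content and length, after whose removal it was -1.14. Leukocytes in the empty-vector cultures are argued against by a median of 0.0541 FPKM over 12 leukocyte markers, with PTPRC at 0.0327 and LYZ at 0.0754, while CD68, the 1 that these cells express, was at 39.3. The level of CARM1 may be the cause, but the design holds 2 levels of CARM1, 1 per group, and any other difference between the transduced populations runs with them. Other CARM1 levels or separate transductions would be needed to tell these apart.

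The ferritin chains moved apart, FTL up and FTH1 down. The ratio of FTH1 to FTL was 4.22 ± 0.102 with empty vector and 1.51 ± 0.0458 with CARM1 (SD, n = 3 each). A factor applied to a whole library cannot change this ratio, whose lowest empty-vector value was 2.65 times the highest CARM1 value, and under quantile normalization, which is not such a factor, the log2 fold changes were -0.24 for FTH1 and 0.78 for FTL and both were called. With GC and length trends removed, the log2 fold changes were -0.58 for FTH1 and 1.02 for FTL, and the smaller of them in units of its SE was 21.1, which argues against such trends as the whole cause. Reads shared with processed pseudogenes stay open, because the table holds 0 pseudogenes named for FTH1 or FTL, and a change in transcription or message stability with CARM1 is an untested alternative.

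The adult globin genes were seen almost only with empty vector, HBB at 3.66, 4.71 and 5.48 FPKM in the empty-vector libraries and listed at 0, 0 and 0.125 in the CARM1 libraries. HBA1 had a mean of 3.96 FPKM with empty vector and was listed at 0, 0.0403 and 0 with CARM1, and HBA2 had a mean of 3.68 and was listed at 0, 0.034 and 0. These 3 were the only genes at 3 FPKM or more in 1 group and under 0.1 in the other. Those limits were chosen after the values were seen. ELF3, not a globin, lay just outside them, at a mean of 2.79 FPKM with empty vector and 0.0251 with CARM1. A library scaling is argued against, since 0.430% of the other genes at 3 to 5 FPKM with empty vector, 5 of 1163, lay under 0.5 with CARM1. Blood RNA in the empty-vector libraries may be a source and stays open. The erythroid genes ALAS2, at 0.112 FPKM or less, and AHSP, at 0 in these libraries, cannot decide it. With the globins themselves this low, a gene at a small share of HBB would lie near the floor either way. HBE1, an embryonic globin that adult red cells lack, was at 1.32 FPKM or more in the empty-vector libraries. It was also at 0.601 to 1.14 in the CARM1 libraries, so it does not decide between blood RNA and transcription in the empty-vector cells themselves.

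The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 7302 genes and the highest of the others 1. For gene lists the real split called 11 and the others 4 to 7. Camera with the preset correlation thus called lists in splits where almost no gene was called. In each case 1 split, the real one, reached the real value. The other splits mix the groups and keep part of the contrast between them.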
